A study of Mus musculus with 6 samples.

How the data were processed

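RNA-seq was measured in 6 libraries of mouse bone marrow cells, 3 from mice given Onway (Onway 1, Onway 2 and Onway 3) and 3 from untreated mice (Control 4, Control 5 and Control 6). Per the labels, the mice were female BALB/c animals from which a tumour of 4T1, a mouse mammary carcinoma cell line, had been resected, and Onway was given by gavage for 2 weeks. What Onway contains is not given in the sources used here. The labels carry day 0 for each Control library and day 14 for each Onway library, so treatment and labelled day cannot be told apart. The labels name no batch, and the replicate numbers of the groups are not shared, so no pairing was used. They call the libraries samples of separate groups without stating that each came from its own mouse, so p-values measure the spread between these libraries.

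RNA was isolated with a column kit and libraries were made with a SMARTer mRNA kit, per the labels' protocols. Whether the libraries kept the strand of the RNA is not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the quantifier and their versions are not given in the sources used here. The authors deposited 1 table of TPM (transcript abundance scaled to a fixed library total) for 158850 transcripts, of which 142430 carried Ensembl identifiers and 16416 carried identifiers starting with MSTRG, the prefix of newly assembled transcripts. TPM is scaled within each library, and the TPM values of each library summed to 1e+06. It keeps no read depth, so the number of reads per library is unknown, and neither counting intervals nor detection limits are given. The table also gives a length for each transcript, deposited by the authors, which was not used.

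The table names the Onway columns by number with another prefix than the titles, and they were matched to Onway 1, Onway 2 and Onway 3 by that number. The authors deposited a group mean of TPM beside the libraries. For every transcript, 4 times the deposited Onway mean was at least the sum of the 3 matched Onway libraries within a tolerance of 0.011 TPM, while 4 times the deposited Control mean fell short of that sum for 30461 transcripts. No deposited group mean departed from a mean of 4 values with 2 decimals, and 71142 Control means and 69692 Onway means could not be means of 3 such values. A further library in each group therefore entered the authors' means. It was not analysed here as a library, and the deposited means are given as the authors' values, with no error. What 4 times a deposited mean leaves beyond the 3 libraries was computed after seeing the data. Over all genes it came to 1e+06 TPM in each group, the total of a library, and it entered no test.

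TPM values of transcripts were summed to 56496 genes. Symbols were those of the deposited table. In GENCODE M21, an annotation of GRCm38, 97.1% of the Ensembl transcripts were found, and coordinates of genes are from that annotation. Genes with a mean of at least 1 TPM over the 6 libraries were tested (14192 genes, 795 of them without a symbol). Values were analysed as log2(TPM + 1), which understates the change of genes near 1 TPM. The design fixed before the data were examined named a quasi-likelihood test for counts and, for normalized values, limma with a mean-variance trend and robust empirical Bayes moderation. Because the values are TPM, the latter was used (limma 3.58.1 in R 4.3.3), on all 6 libraries with no covariate. All tests were two-sided unless stated. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Standard errors are limma's moderated values. Level comparisons of single measures used an exact permutation test over the 20 assignments of 6 libraries to 3 and 3, whose smallest p is 0.1.

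Before the data were examined, 41 lists of cell type markers and pathway genes with 896 symbols were fixed, and 890 symbols were found in the table. The 40 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which compares the members with all other tested genes. The test was repeated with a correlation estimated for each list, and with fry, a rotation test of whether the members move on balance one way. List p-values were Benjamini-Hochberg adjusted over the 40 lists. Gene counts per list are given over all tested genes and adjusted over the list alone. Gene Ontology terms in the deposited table with 10 to 500 tested genes (2860 terms) were compared with the called genes by a one-sided Fisher's exact test, against 13269 tested genes with a term.

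Genes named in the text follow a rule fixed beforehand. They are the 12 genes per direction with the largest log2 fold change past the threshold, with no overlap between the groups, at least 1 TPM in the higher group and a symbol that is not a predicted gene name. To them were added the 2 to 4 members of each described list with the smallest p, and a fixed panel of 18 marrow genes. Any other named gene is said to have been chosen after its values were seen. The fit was tested on simulated data with 200 changed genes among the 14192 in a comparison of 3 against 3 libraries. It recovered 16% of genes raised by 1 on the log2 scale, 82% raised by 2, 90% raised by 4 and 22% lowered by 1. Of its 115 calls, 10 were unchanged genes. The simulated noise was independent between genes, unlike real genes that vary together across libraries, so these shares need not hold in the data.

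Alternatives fixed beforehand were median-of-ratios and upper-quartile scaling of TPM, no filter, a stricter filter (1 TPM in 3 libraries and a mean of 5), removal of haemoglobin, mitochondrial and ribosomal RNA genes before rescaling, pseudocounts of 0.1 and 5, limma's treat against a fold of 1.2, tests of transcripts, and leaving out each library. Leaving out the 2 libraries with the highest haemoglobin share, and using that share as a covariate, were added after seeing the data.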

Results

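Gene expression was measured by RNA-seq in bone marrow cells of BALB/c mice after resection of a tumour of 4T1, a mouse mammary carcinoma line. The groups were 3 libraries from mice given Onway by gavage for 2 weeks and 3 libraries from untreated mice (Control). The comparison asks which transcripts differed in marrow between treated and untreated animals after surgery. Values are TPM as the authors deposited them, summed to genes, and are given as mean ± SD (n = 3 per group). Between 13354 and 14252 genes reached 1 TPM in a library. The 10 most abundant genes took 35.7% ± 2.33 of the TPM in Control and 35.9% ± 8.24 in Onway (exact permutation p = 1). Haemoglobin genes made up 26.6%, 11.6% and 18.3% in Control 4, Control 5 and Control 6, and 13.3%, 9.38% and 33.9% in Onway 1, Onway 2 and Onway 3. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.924 to 0.953 within groups and 0.894 to 0.924 between groups. The first principal component held 41.5% of the variance and separated the groups, and the second held 21.6% and set Control 4 and Onway 3, the libraries with the highest haemoglobin shares, apart from the others.

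Marrow from Onway-treated mice carried far less RNA of skeletal muscle, bone, stroma, endothelium and megakaryocytes than Control marrow, and more RNA of immediate early genes. Acta1, skeletal muscle actin, fell from 391 ± 297 to 0.563 ± 0.535 TPM (log2 fold change −7.68, SE 0.68, limma with Benjamini-Hochberg adjusted p = 0.0036). Pf4, the platelet chemokine, fell from 801 ± 34.1 to 52.9 ± 6.21 TPM (log2 fold change −3.90, SE 0.17, adjusted p = 0.00040). Fos, an immediate early transcription factor, rose from 14.8 ± 9.22 to 456 ± 255 TPM (log2 fold change 4.83, SE 0.57, adjusted p = 0.0089). In all, 424 of 14192 tested genes were lower and 33 were higher in Onway, and 1897 genes had an unadjusted p under 0.05. Of the lower genes, 193 fell by at least 2 on the log2 scale, and 71 belonged to the lists of the 5 tissues and cell types named above. Of all 14192 tested genes, 2623 (18.5%) had no overlap between the groups, where chance leaves 10% of genes without overlap. The authors' group means include a further value per group, and these values did not show this difference. For the muscle list they leave 28.1 TPM for that value in Control and 30.7 TPM in Onway, and for Pf4 381 and 468 TPM. Leaving out Control 4 and Onway 3, chosen after seeing the data, changed the counts to 207 lower and 97 higher, so the higher share of calls moved from 7.22% to 31.9%. Leaving out 1 library at a time gave 246 lower and 16 higher genes without Onway 2, 254 and 72 without Onway 3, 285 and 71 without Onway 1, and 318 and 87 without Control 4.

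**Figure D1:**
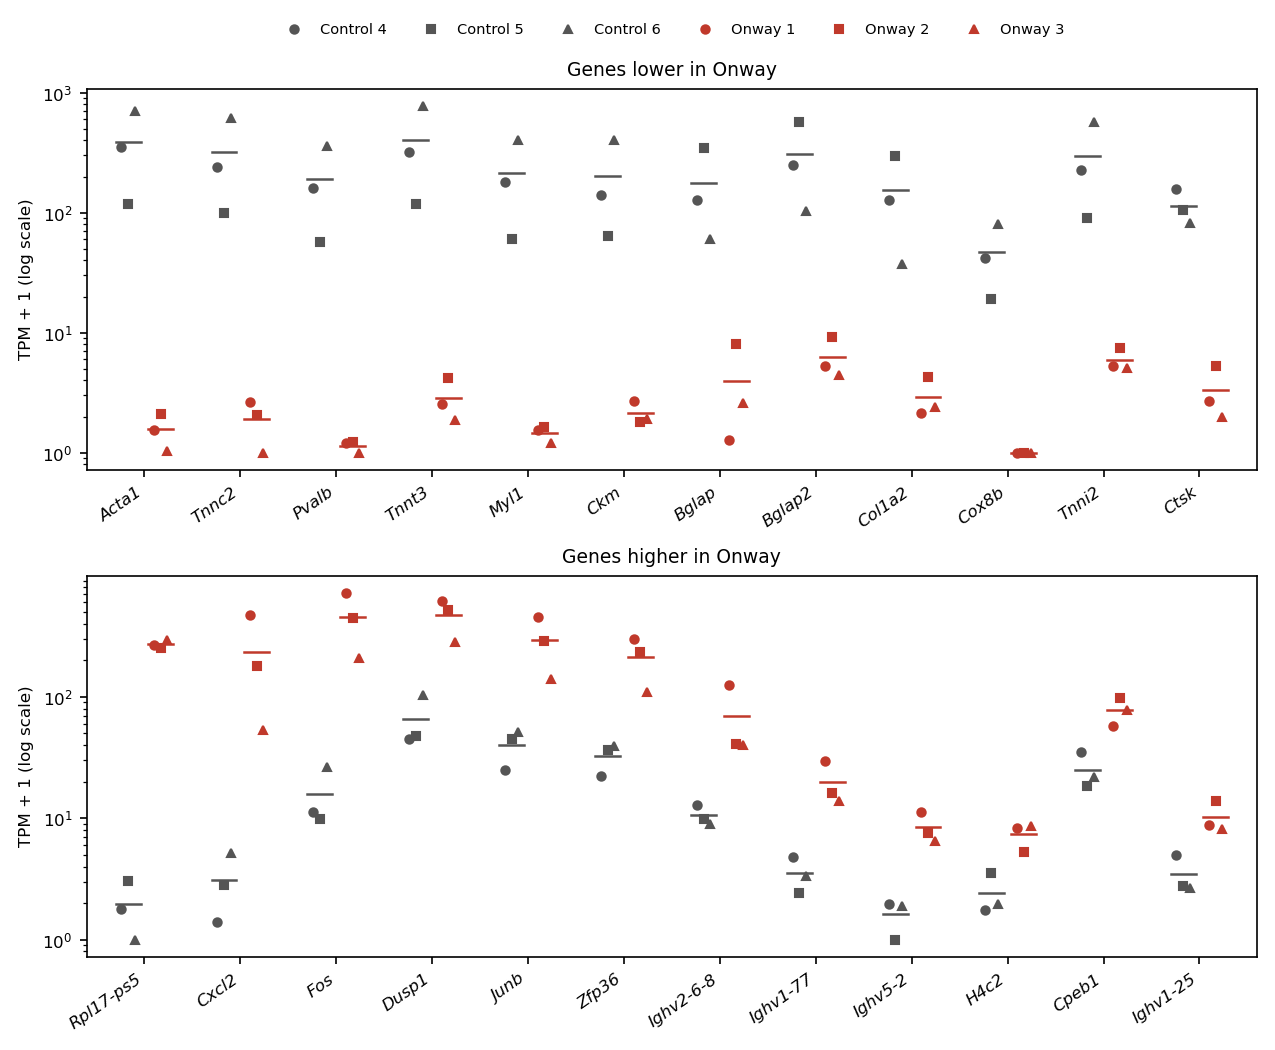
TPM + 1 on a log axis of 12 genes per direction, with 1 point per library and a line at the group mean. They had the largest fold change past the threshold among genes with a symbol that is not a predicted gene name. All had no overlap between the groups and at least 1 TPM in the higher group. Acta1 had a mean of 391 TPM in Control and 0.563 TPM in Onway, and Fos had means of 14.8 and 456 TPM.

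Skeletal muscle transcripts were present in all 3 Control libraries and close to absent from all 3 Onway libraries. Of the 15 tested skeletal muscle genes, 12 fell, 15 did so adjusted over the list alone, and the median log2 fold change was −4.89. The TPM of the list summed to 2166, 794 and 5092 in Control 4, Control 5 and Control 6 and to 25.1, 31.1 and 24.1 in Onway 1, Onway 2 and Onway 3, a 100-fold difference of means (exact permutation p = 0.1, the smallest this design allows). Besides Acta1, at chromosome 8, 123891769 to 123894751 (GRCm38), these were Pvalb, a calcium buffer of fast fibres (191 ± 154 against 0.143 ± 0.124 TPM, adjusted p = 0.0039), Myl1, a fast-fibre myosin light chain (214 ± 175 against 0.470 ± 0.238 TPM, adjusted p = 0.0054), and the troponins Tnnc2 (316 ± 264 against 0.903 ± 0.840 TPM, adjusted p = 0.0068), Tnnt3 (403 ± 336 against 1.87 ± 1.2 TPM, adjusted p = 0.0077) and Tnni2 (294 ± 248 against 4.92 ± 1.36 TPM, adjusted p = 0.013). Ckm, muscle creatine kinase, fell from 201 ± 176 to 1.14 ± 0.491 TPM (adjusted p = 0.0070). Cox8b, a muscle form of a cytochrome oxidase subunit, was at 46.3 ± 31.3 TPM in Control and listed at 0 in every Onway library (adjusted p = 0.0024). Camera gave the list an adjusted p of 3e-24, and adjusted p = 0.24 with an estimated correlation. Without Onway 1 the adjusted p of Tnnt3 was 0.056 and that of Tnni2 was 0.078. Tnni2 also lost its call without Control 4 (0.069) and without Onway 3 (0.065), and all 8 genes lost theirs without both Control 4 and Onway 3 (0.095 to 0.16).

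Bone-forming and bone-resorbing cell markers fell together. Of 16 tested osteoblast and osteoclast genes 15 fell, 16 did so adjusted over the list alone, and the median log2 fold change was −4.26. Dmp1, a matrix protein of osteocytes, fell from 21.5 ± 6.88 to 0.127 ± 0.121 TPM (log2 fold change −4.28, SE 0.25, adjusted p = 0.00048). Spp1, osteopontin, fell from 206 ± 42.2 to 9.82 ± 3.42 TPM, Ctsk, the collagen-degrading protease of osteoclasts, from 114 ± 38 to 2.31 ± 1.74 TPM, and Mmp13, a collagenase, from 42.6 ± 17.1 to 1.34 ± 0.936 TPM (adjusted p = 0.00051, 0.0012 and 0.0014). Col1a2, a chain of type I collagen, fell from 153 ± 131 to 1.94 ± 1.16 TPM (adjusted p = 0.026). The osteocalcin genes Bglap (177 ± 150 against 2.96 ± 3.56 TPM, adjusted p = 0.045) and Bglap2 (305 ± 238 against 5.32 ± 2.55 TPM, adjusted p = 0.012) are near-identical copies, so their separate values are uncertain. The camera test gave an adjusted p of 8.5e-26, and adjusted p = 0.14 with an estimated correlation. Dmp1, Spp1, Ctsk and Mmp13 stayed past the threshold without any single library. Leaving out Control 4, Onway 1 or Onway 3 ended the calls of Bglap (adjusted p = 0.17, 0.12 and 0.10), Bglap2 (0.062, 0.070 and 0.059) and Col1a2 (0.12, 0.12 and 0.084), as did leaving out Control 5 (0.11) or Control 6 (0.083) for Bglap and Onway 2 for Col1a2 (0.060). Without both Control 4 and Onway 3 these 3 genes had adjusted p-values of 0.21, 0.16 and 0.19.

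Most tested stromal and endothelial genes fell in Onway as well, while 1 fat cell gene did. Of 17 tested stromal and fibroblast genes 15 fell, 17 adjusted over the list alone, with a median log2 fold change of −2.19. Dcn, the matrix proteoglycan decorin, fell from 37.3 ± 11 to 1.15 ± 0.240 TPM, and Igfbp5, which binds insulin-like growth factors, from 52.3 ± 15.1 to 4.04 ± 0.372 TPM (adjusted p = 0.00048 and 0.00052). Esm1 and Col6a1 fell by 2.51 on the log2 scale each (SE 0.25 and 0.27). Of 17 endothelial genes 10 fell, 14 adjusted over the list alone, with a median of −1.39. They included Esam (12.7 ± 0.907 against 1.68 ± 0.138 TPM), Plvap (12 ± 1.1 against 2.96 ± 0.0896 TPM), the junction protein Cldn5 (6.44 ± 0.560 against 0.973 ± 0.220 TPM) and Emcn (4.08 ± 0.578 against 0.683 ± 0.306 TPM), with adjusted p-values of 0.00052, 0.0016, 0.0017 and 0.0083. Of 8 adipocyte genes 1 fell, 6 adjusted over the list alone. It was Car3, a carbonic anhydrase abundant in both fat and skeletal muscle, from 27.3 ± 1.81 to 1.57 ± 0.425 TPM (adjusted p = 0.00048). Fabp4 was at 52.9 ± 17.2 and 11.1 ± 7.17 TPM and Adipoq at 13.3 ± 7.68 and 2.03 ± 1.30 TPM (adjusted p = 0.053 and 0.063). Without Control 5 both passed (0.043 and 0.020), as did Fabp4 without Onway 3 (0.017) and Adipoq without both Control 4 and Onway 3 (0.045), where Emcn lost its call (0.074). The camera adjusted p-values were 1.4e-24 for stroma, 4.1e-17 for endothelium and 7.8e-06 for fat, and adjusted p = 0.14, 0.14 and 0.24 with an estimated correlation.

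Among genes of resident macrophages 1 fell over all genes. Of 16 tested tissue macrophage genes 15 had a negative sign and 11 fell adjusted over the list alone, and the median log2 fold change was −0.96. The called gene was Vcam1, an adhesion molecule also carried by stroma and endothelium (86.7 ± 16.5 against 34.1 ± 0.990 TPM, log2 fold change −1.30, SE 0.19, adjusted p = 0.0090, 0.055 without Onway 2 and 0.062 without both Control 4 and Onway 3). The complement subunits C1qc and C1qb were at 54.9 ± 12.7 and 58.6 ± 15.2 TPM in Control and at 24.2 ± 6.01 and 25.6 ± 6.51 TPM in Onway (adjusted p = 0.057 and 0.066), and Spic, a transcription factor of red pulp macrophages, was at 9.33 ± 3.51 and 2.91 ± 0.987 TPM (adjusted p = 0.061). Without Control 5 all 3 of these passed (adjusted p = 0.033 for C1qc, 0.040 for C1qb and 0.024 for Spic). Camera gave an adjusted p of 1e-08, and adjusted p = 0.33 with an estimated correlation.

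Megakaryocyte and platelet genes were lower in Onway in 19 of 20 tested cases, with little spread among the 3 libraries of a group. All 19 fell both over all genes and adjusted over the list alone, and the median log2 fold change was −3.16. The list summed to 2588 ± 194 TPM in Control and 192 ± 52.2 TPM in Onway, a 13.4-fold difference (exact permutation p = 0.1). Besides Pf4, Gp5, a subunit of the platelet von Willebrand factor receptor, fell from 45.7 ± 5.06 to 3.40 ± 1.11 TPM, Mmrn1, a platelet granule protein, from 22.9 ± 0.993 to 2.07 ± 0.540 TPM, and Rab27b, a granule-secretion GTPase, from 20.8 ± 1.29 to 1.61 ± 0.244 TPM (adjusted p = 0.00048 for each). The calls of these 4 genes held without any single library. The difference was smaller between the authors' means, at 696 and 157 TPM for Pf4 (4.44-fold), where the median log2 ratio of the list was −2.01 against −3.10 between the means of the 3 libraries. The authors' means contain those libraries, and the further value they leave showed no fall. Over the list it was 1211 TPM in Control and 1411 TPM in Onway. With camera the adjusted p was 1.1e-38, and adjusted p = 0.18 with an estimated correlation. Fry gave an adjusted p of 0.0021, the same as for the bone, stromal and endothelial lists.

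Stem and progenitor genes divided. Of 17 tested members 4 fell, 6 adjusted over the list alone with 1 higher, and the median log2 fold change was −0.13. The 4 were Slamf1, a surface marker of stem cells that megakaryocytes also carry (14.3 ± 0.896 against 1.28 ± 0.306 TPM, adjusted p = 0.00051), Ctla2a (95.3 ± 14.5 against 22.0 ± 3.23 TPM, adjusted p = 0.0014), Angpt1, an angiopoietin (9.69 ± 0.526 against 2.37 ± 0.272 TPM, adjusted p = 0.0019), and Tek, its receptor, which endothelium carries (2.75 ± 0.595 against 0.487 ± 0.172 TPM, adjusted p = 0.022). Tek lost its call without Control 4, Control 6, Onway 2 or Onway 3 (adjusted p = 0.077, 0.11, 0.087 and 0.077), and without both Control 4 and Onway 3 (0.14). Kit, the stem cell factor receptor, was at 15.1 ± 1.49 and 14.6 ± 1.18 TPM (adjusted p = 0.94). For this list camera gave an adjusted p of 0.0012, and adjusted p = 0.43 with an estimated correlation.

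**Figure D2:**
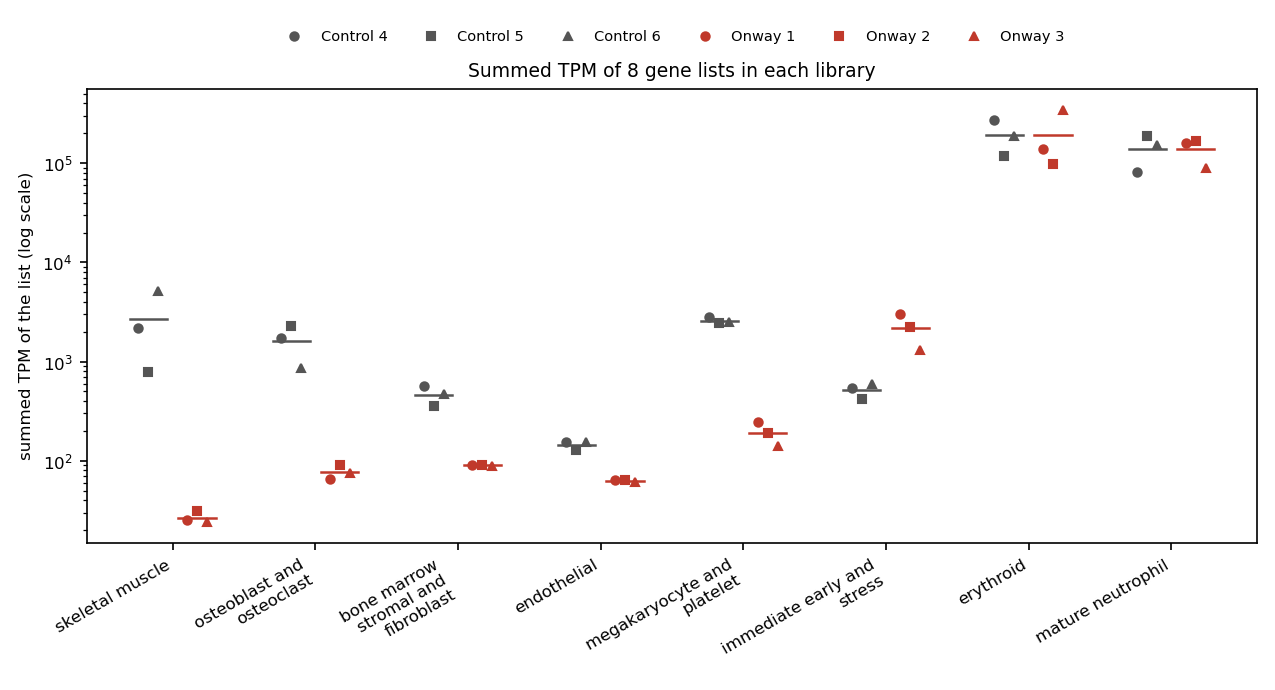
Summed TPM of 8 gene lists on a log axis, with 1 point per library and a line at the group mean. The muscle list summed to 794 to 5092 TPM in Control and 24.1 to 31.1 TPM in Onway, the platelet list to 2588 and 192 TPM on average, and the erythroid and mature neutrophil lists overlapped between the groups.

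Of 20 tested immediate early genes 6 rose in Onway over all genes. All 20 tested members had a positive sign, 13 rose adjusted over the list alone, and the median log2 fold change was 1.50. Besides Fos, at chromosome 12, 85473890 to 85477273 (GRCm38), the 6 past the threshold over all genes included Dusp1, a phosphatase of MAP kinases (64.1 ± 33.0 against 470 ± 168 TPM, adjusted p = 0.013), Junb (39.2 ± 13.7 against 294 ± 158 TPM, adjusted p = 0.032) and Jund (29.3 ± 2.44 against 84.0 ± 7.23 TPM, adjusted p = 0.0023), partners of Fos in the AP-1 transcription factor, Zfp36, which destabilises cytokine mRNA (31.6 ± 9.18 against 212 ± 96.2 TPM, adjusted p = 0.019), and Klf2 (15.3 ± 1.45 against 42.2 ± 3.15 TPM, adjusted p = 0.0027). The list summed to 540, 418 and 595 TPM in Control 4, Control 5 and Control 6 and to 3031, 2252 and 1314 TPM in Onway 1, Onway 2 and Onway 3. Tested with camera, the list had an adjusted p of 8e-14, and adjusted p = 0.24 with an estimated correlation. Fos, Jund and Klf2 stayed past the threshold without any single library, but without both Control 4 and Onway 3 Fos had an adjusted p of 0.073 and Dusp1 one of 0.071. Without Onway 2 the adjusted p was 0.080 for Dusp1, 0.10 for Zfp36 and 0.12 for Junb. Junb also lost its call without Control 4 (0.076), Control 5 (0.088), Control 6 (0.065) or Onway 1 (0.052). The authors' means for Fos were 75.3 TPM in Control and 360 TPM in Onway, and they contain the same 3 libraries. The further value they leave ran the other way, with Fos at 257 TPM in Control and 74.1 TPM in Onway. For the list it was 1549 TPM in Control and 765 TPM in Onway.

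Among NF-kB and inflammatory cytokine genes, 1 of 24 tested members rose and 1 fell, 13 rose and 1 fell adjusted over the list alone, and the median log2 fold change was 0.92. Cxcl2, a neutrophil-attracting chemokine, rose from 2.12 ± 1.89 to 233 ± 213 TPM (log2 fold change 5.93, SE 0.92, adjusted p = 0.035). The further value per group in the authors' means ran the other way for Cxcl2. Those means leave 236 TPM for it in Control and 13.9 TPM in Onway. Il1a, interleukin 1 alpha, fell from 3.85 ± 0.929 to 0.437 ± 0.0208 TPM (log2 fold change −1.74, SE 0.22, adjusted p = 0.0052). Ccl3 was at 4.86 ± 1.84 and 30.6 ± 16.0 TPM and Ccrl2 at 7.27 ± 2.57 and 30.1 ± 14 TPM (adjusted p = 0.068 and 0.072), and both passed without Onway 3 (0.011 and 0.029). The camera adjusted p was 3e-08, and adjusted p = 0.33 with an estimated correlation. The call of Cxcl2 ended without Control 4, Control 5, Control 6, Onway 1 or Onway 2 (adjusted p = 0.12, 0.18, 0.12, 0.058 and 0.089), and without both Control 4 and Onway 3 those of Cxcl2 (0.055) and Il1a (0.059) ended.

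Other genes with large increases belonged to no fixed list. Rpl17-ps5, a processed pseudogene of the ribosomal protein gene Rpl17 at chromosome 5, 22612628 to 22613182 (GRCm38), rose from 0.953 ± 1.04 to 270 ± 20.9 TPM (log2 fold change 7.26, SE 0.38, limma with Benjamini-Hochberg adjusted p = 0.00048). Rpl17 itself was at 1067 ± 94.7 TPM in Control and 798 ± 62.3 TPM in Onway, and reads of these near-identical copies may be assigned to either. The authors' means of Rpl17-ps5 were 66.4 TPM in Control and 206 TPM in Onway, and they contain the same 3 libraries. The further value they leave for Rpl17-ps5 was 263 TPM in Control and 13.6 TPM in Onway. Cpeb1, which controls the poly(A) tail of mRNA, rose from 24.2 ± 8.61 to 76.8 ± 20.2 TPM (adjusted p = 0.024), and H4c2, a histone H4 gene with many copies, from 1.42 ± 0.987 to 6.40 ± 1.83 TPM (adjusted p = 0.041). Of 222 tested immunoglobulin variable segments, which resemble each other, 5 rose, among them Ighv2-6-8 from 9.53 ± 2.04 to 68.1 ± 49.4 TPM, Ighv1-77 from 2.54 ± 1.21 to 18.7 ± 8.39 TPM, Ighv5-2 from 0.613 ± 0.532 to 7.43 ± 2.49 TPM and Ighv1-25 from 2.48 ± 1.29 to 9.24 ± 3.12 TPM (adjusted p = 0.043, 0.011, 0.0079 and 0.042). The authors' means of Ighv5-2 ran the other way, at 6.89 TPM in Control and 5.89 TPM in Onway. Without Onway 2 the adjusted p was 0.11 for Cpeb1, 0.075 for H4c2, 0.079 for Ighv2-6-8, 0.061 for Ighv1-77, 0.056 for Ighv5-2 and 0.15 for Ighv1-25. Without Onway 3 it was 0.10 for Cpeb1, 0.13 for H4c2, 0.077 for Ighv2-6-8 and 0.087 for Ighv1-25, and without Control 6 it was 0.084, 0.13, 0.16 and 0.13 for the same 4 genes. H4c2 and Ighv2-6-8 also lost their calls without Control 4 (0.097 and 0.10), H4c2 and Ighv1-25 without Onway 1 (0.11 and 0.074), and Ighv2-6-8 and Ighv1-25 without Control 5 (0.15 and 0.098). Without both Control 4 and Onway 3 the adjusted p was 0.062 for Cpeb1, 0.17 for H4c2 and 0.15 for Ighv2-6-8.

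The B cell lists were higher in Onway as groups with camera, at adjusted p = 4e-07 for progenitor and 4.1e-08 for mature B cell genes, and adjusted p = 0.43 and 0.33 with an estimated correlation. No member passed the threshold over all genes in all 6 libraries. Of 21 progenitor B cell genes 21 had a positive sign (median log2 fold change 0.85), and of 19 mature B cell genes 18 did (median 1.36). None of either passed over all genes or adjusted over the list alone. Pax5, the B lineage transcription factor, was at 9.37 ± 1.44 and 28.8 ± 13.7 TPM (adjusted p = 0.17), Cd79a, a B cell receptor chain, at 45.1 ± 11.5 and 145 ± 81.2 TPM (0.30), Vpreb1, a surrogate light chain, at 38.9 ± 28.0 and 50.4 ± 16.8 TPM (0.73), and Pou2af1 and Ms4a1 at 22.8 ± 4.55 and 4.25 ± 3.46 TPM in Control and 63.0 ± 27.7 and 17.2 ± 10.1 TPM in Onway (0.17 and 0.36). Without Onway 1, Pax5 (adjusted p = 0.0068), Cd79a (0.0088) and Pou2af1 (0.0094) passed. The MHC class II list had 14 of 14 members with a positive sign and a median of 0.93, with none past the threshold and 1 adjusted over the list alone. Its members Cd74 and H2-DMb2 were at 131 ± 52.5 and 15.9 ± 3.89 TPM in Control and 331 ± 151 and 39.5 ± 14.9 TPM in Onway (adjusted p = 0.25 and 0.082). Of 15 plasma cell genes 13 had a positive sign (median 0.86), among them Mzb1 (28.7 ± 8.26 against 52.0 ± 9.31 TPM, adjusted p = 0.18) and Irf4 (7.24 ± 2.09 against 18.0 ± 6.93 TPM, 0.16, and 0.034 without Onway 1). The camera adjusted p-values were 3.8e-07 for MHC class II and 0.00038 for plasma cell genes, and adjusted p = 0.33 and 0.38 with an estimated correlation.

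T and NK cell lists showed the same sign with lower levels. Of 13 NK and cytotoxic genes 13 had a positive sign (median log2 fold change 0.46), and none passed over all genes or adjusted over the list alone. Ccl5 was at 11.6 ± 5.08 and 30.3 ± 11 TPM (adjusted p = 0.18), Klrd1 at 2.87 ± 0.136 and 6.49 ± 2.61 TPM (0.19) and Ncr1 at 3.10 ± 0.179 and 5.20 ± 0.981 TPM (0.23). Of 16 T cell genes 14 had a positive sign (median 0.45), 1 fell over all genes, and 1 rose and 1 fell adjusted over the list alone. The falling gene was Lat, an adaptor of the T cell receptor that megakaryocytes and platelets also carry (29.8 ± 1.89 against 6.48 ± 1.58 TPM, adjusted p = 0.0014). Trac, the constant region of the T cell receptor alpha chain, was at 0.883 ± 0.595 and 3.94 ± 1.30 TPM (adjusted p = 0.068) and Cd3e at 0.923 ± 0.446 and 2.57 ± 1.16 TPM (0.29). The camera adjusted p was 0.00080 for NK and 0.0085 for T cell genes, and adjusted p = 0.38 and 0.57 with an estimated correlation. Without Onway 3 the adjusted p was 0.052 and 0.40, and without both Control 4 and Onway 3 it was 0.10 and 0.56.

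No granulocyte gene passed the threshold, and the lists differed in sign. The 14 neutrophil primary granule genes, made early in the lineage, had a median log2 fold change of −0.64 with 11 of negative sign, while 15 of 17 secondary and tertiary granule genes and 20 of 24 mature neutrophil genes had a positive sign (medians 0.29 and 0.44). No member of the 3 lists passed over all genes or adjusted over the list alone, and no test compared the lists with each other. Elane, neutrophil elastase, was at 1565 ± 461 and 836 ± 261 TPM (adjusted p = 0.26), Mpo, myeloperoxidase, at 1848 ± 436 and 1175 ± 384 TPM (0.40) and Fcnb at 344 ± 152 and 131 ± 37.4 TPM (0.22, and 0.022 without Control 4). Ltf, lactoferrin, was at 3843 ± 1011 and 4643 ± 1213 TPM (0.74) and Mmp8 at 375 ± 95.0 and 541 ± 140 TPM (0.49). Cxcr2, a chemokine receptor of mature cells, was at 145 ± 53 and 246 ± 112 TPM (0.60), Il1b at 65.7 ± 54.3 and 301 ± 205 TPM (0.41) and S100a8, a calcium-binding protein, at 41272 ± 16083 and 37234 ± 10995 TPM (0.94). Camera gave adjusted p-values of 0.0037, 0.045 and 0.017 for the primary, secondary and mature lists, and adjusted p = 0.68, 0.80 and 0.82 with an estimated correlation. Without Control 4 the mature list turned to a median of −0.10 (adjusted p = 0.64) and the secondary list went to 0.05 (0.82). Without Onway 1 they were at 0.19 (0.16) and 0.11 (0.43), and the primary list without Onway 3 was at −0.32 (0.055).

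Monocyte genes had a positive sign in 19 of 20 members, with a median log2 fold change of 0.52. None rose over all genes and 2 did adjusted over the list alone, Pld4 (44.3 ± 3.83 against 89.5 ± 21.6 TPM, adjusted p = 0.053, and 0.042 without Onway 3) and Irf8, a transcription factor of the lineage (39.4 ± 6.35 against 73.8 ± 14 TPM, 0.071). Csf1r, the receptor of macrophage colony-stimulating factor, was at 37.6 ± 6.10 and 58.2 ± 24.8 TPM (adjusted p = 0.59). Of 20 genes of myeloid-derived suppressor cells, immature myeloid cells that tumours expand, 18 had a positive sign and 1 rose, Junb, with 3 adjusted over the list alone and a median of 0.38. Cebpb was at 11.9 ± 3.76 and 52.3 ± 28.2 TPM and Ptgs2, cyclooxygenase 2, at 0.0967 ± 0.0723 and 5.12 ± 3.91 TPM (adjusted p = 0.059 and 0.077), and passed without Onway 1 (0.036) and without Onway 3 (0.013) respectively. Arg1, arginase, was below 0.6 TPM in every library and was not tested, and Cd274, PD-L1, was at 1.85 ± 0.222 and 2.15 ± 0.739 TPM (0.87). The camera adjusted p was 4.4e-05 for monocyte and 0.0033 for suppressor cell genes, and adjusted p = 0.58 and 0.73 with an estimated correlation. Without Control 4 the suppressor list had a median of 0.07 (adjusted p = 0.28).

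Erythroid and proliferation genes did not separate the groups. The 29 erythroid genes had a median log2 fold change of 0.03 with none called (camera adjusted p = 0.95), and Hba-a1, an alpha globin gene with a near-identical copy, was at 44109 ± 20883 and 44677 ± 34374 TPM (adjusted p = 0.94). Klf1, the erythroid transcription factor, was at 94.3 ± 66.8 and 89.0 ± 22.1 TPM (0.95). The erythroid list followed single libraries. Its median was 0.47 without Control 4 (camera adjusted p = 0.000986), 0.26 without Onway 2 (0.015), −0.40 without Control 5 (0.0049) and −0.21 without Onway 3 (0.0093). The 30 S phase genes had a median of 0.02 and the 32 genes of G2 and M phase one of 0.01, with none called (camera adjusted p = 0.74 and 0.77), and both medians were below 0 after upper-quartile scaling. Mki67, the proliferation marker, was at 192 ± 54.1 and 216 ± 22.2 TPM (adjusted p = 0.77). Without Control 4 the S phase list was at 0.20 (camera adjusted p = 0.000986).

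Metabolic lists moved by small and uniform amounts. All 39 oxidative phosphorylation genes had a negative sign, with a median log2 fold change of −0.31 and none past the threshold over all genes or adjusted over the list alone. Uqcrq, a subunit of complex III, was at 175 ± 7.63 and 111 ± 4.88 TPM (adjusted p = 0.081) and Cox5a at 231 ± 26.6 and 144 ± 25.1 TPM (0.15). Of 22 cholesterol biosynthesis genes 20 had a negative sign (median −0.32), and of 50 ribosomal protein genes 49 did (median −0.13), with none called in either list over all genes or adjusted over the list alone. Rps18 was at 70.2 ± 0.613 and 47.2 ± 7.01 TPM (adjusted p = 0.16). Control 5 had the lowest muscle sum of the Control libraries (794 TPM). It also had the highest oxidative phosphorylation sum (7730 TPM, against 7317 in Control 4 and 7329 in Control 6). This order cannot tell whether muscle RNA added to the list, because the TPM of other genes rises where haemoglobin takes less. Haemoglobin took 26.6%, 11.6% and 18.3% of the TPM in Control 4, Control 5 and Control 6. The camera adjusted p-values were 7.9e-11, 0.00062 and 0.0012, and adjusted p = 0.43, 0.68 and 0.75 with an estimated correlation. Without Control 5 the ribosomal list had an adjusted p of 0.15.

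**Figure D3:**
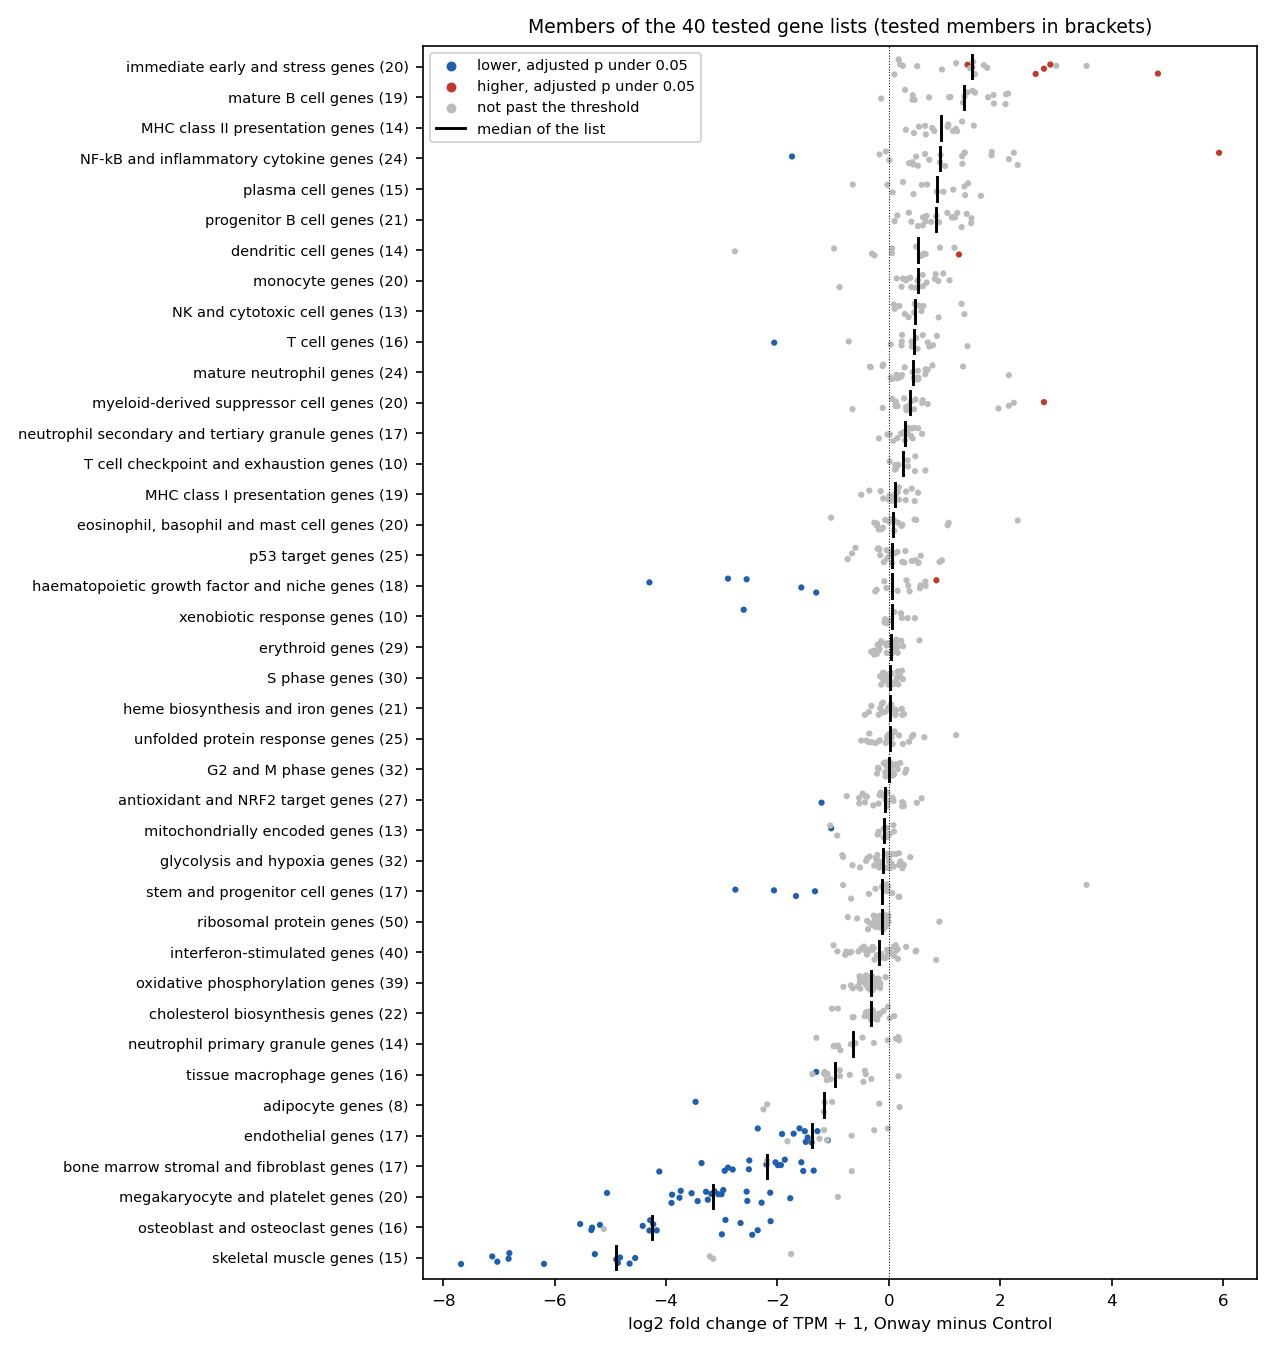
Log2 fold change (Onway minus Control) of each tested member of the 40 gene lists, with the list median as a bar and called genes in colour. The medians run from −4.89 for skeletal muscle to 1.50 for immediate early genes.

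Across the 40 tested lists, 12 were lower and 12 were higher with camera at the preset correlation. None of the 24 held with an estimated correlation, and 8 held with fry. The 8 were the platelet, bone, stromal and endothelial lists (fry adjusted p = 0.0021 each), fat (0.015), muscle (0.016), and stem cell and immediate early genes (0.023 each). With 4 residual degrees of freedom, the estimated correlations were 0.94 for muscle, 0.69 for platelet and 0.34 for immediate early genes. Lists that did not pass were interferon-stimulated genes (median log2 fold change −0.18, adjusted p = 0.11), glycolysis and hypoxia genes (−0.10, 0.22), heme biosynthesis and iron genes (0.02, 0.74), unfolded protein response genes (0.01, 0.69), p53 target genes (0.06, 0.36), MHC class I presentation genes (0.12, 0.25) and T cell checkpoint genes (0.25, 0.058), with none of their members called over all genes or adjusted over the list alone. Some of these passed without 1 library: interferon-stimulated genes without Onway 2 (−0.35, adjusted p = 0.0040) and Control 4 (−0.21, 0.0055), glycolysis genes without Control 4 (−0.21, 0.010) and Onway 1 (−0.17, 0.037), heme genes without Control 4 (0.39, 0.011) and Control 5 (−0.31, 0.019), MHC class I genes without Onway 1 (0.20, 0.036), and checkpoint genes without Control 5 (0.35, 0.040), Control 6 (0.30, 0.026) and Onway 1 (0.27, 0.047). The medians of the p53, heme and unfolded protein response lists were below 0 after upper-quartile scaling. Of the mammary epithelial and tumour cell list 4 members were expressed and no list test was run. Its members Spint2, Cdh1 and Krt18 were at 35.5 ± 8.76, 1.77 ± 0.591 and 2.62 ± 0.700 TPM in Control and at 25.9 ± 1.66, 2.11 ± 1.12 and 2.53 ± 0.837 TPM in Onway (adjusted p = 0.46, 0.90 and 0.96).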

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

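The authors' group means, which include a value per group beyond the 3 libraries, drew attention because they lie above the Control libraries for genes called higher in Onway. For 17 of the 33 genes higher in Onway, the deposited Control mean was above all 3 Control libraries. That mean was 75.3 TPM for Fos (libraries 8.81 to 25.4 TPM), 60.6 TPM for Cxcl2 (0.39 to 4.14 TPM) and 66.4 TPM for Rpl17-ps5 (0 to 2.06 TPM). The log2 difference between the deposited means, on the log2(TPM + 1) scale, was smaller than that between the means of 3 libraries for 32 of the 33 higher and 422 of the 424 lower genes, which were picked for a large difference in those libraries. The deposited means contain the same 3 libraries, and over all tested genes 12593 of 14192 had the same direction in both. Of the called genes all but 2 did, the exceptions being Ighv5-2 (6.89 TPM in Control and 5.89 TPM in Onway) and Gm28872 (36.4 and 27.7 TPM, named after its values were seen).

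What 4 times a deposited mean leaves beyond the 3 libraries came to 1e+06 TPM over all genes in each group, as for 1 more library, and this pair of values did not show the main differences. It left for Control and Onway 28.1 and 30.7 TPM over the muscle list, 87.9 and 84.2 TPM over the bone list, 172 and 153 TPM over the stromal list, 85.9 and 87.4 TPM over the endothelial list and 1211 and 1411 TPM over the platelet list. For immediate early genes it left 1549 and 765 TPM, with Fos at 257 and 74.1 TPM, so the value in Control was the higher. A single value per group allows no test. Which mice these were is not given in the sources used here, and neither an exchange of labels nor a batch that the labels do not give was tested.

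Of the tests that follow, those of scaling and of the erythroid share were written before their results were seen, and those of a fixed tissue mix, of muscle, of heat-shock genes and of Rpl17 were chosen after seeing the pattern, and the haemoglobin covariate was added after seeing the data.

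Lower muscle, bone, stromal, endothelial and platelet genes could come from scaling by a few abundant genes, but after median-of-ratios scaling the median log2 fold change of the 5 lists was −2.95 (SE over genes 0.18). One tissue carried over with a fixed mix of these cells would give the lists equal ratios between Control libraries. Their median log2 ratios of Control 6 to Control 5 instead ranged over 3.28, from −0.59 for bone to 2.69 for muscle. Tissues carried over in amounts that differ between libraries would also give unequal ratios. That was not tested for bone, stroma, endothelium or platelets. For the skeletal muscle list, the log2 ratio of Control 6 to Control 5 had an SD of 0.199 over genes. The Onway sum was 0.998% of Control, with Acta1 at 391 TPM and Tnnt3 at 403 TPM in Control. Of 15 members, 5 were at 1 TPM or more in Onway and 0 were in another list. Skeletal muscle carried into these 3 Control preparations could give this pattern, but the pattern does not single it out. The platelet list had a smaller SD (0.135), with the Onway sum at 7.44% of Control. The SD was 0.452 for endothelium, 0.638 for stroma and 1.53 for bone. The low Onway sum restates the fall that prompted the test. In the 6 libraries treatment and labelled day cannot be told apart, since each Control library carries day 0 and each Onway library day 14. An effect of Onway was not tested apart from these and stays open, and the value left in the Control mean had little muscle and bone RNA.

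For the higher immediate early genes, the haemoglobin share as a covariate left a median log2 fold change of 1.50 (SE over genes 0.28), which decides nothing about the erythroid share, because its mean was 18.8% in Control and 18.9% in Onway and so it has no way to move the fold. A median over a list cannot exclude handling stress of the heat-shock type that raises only some members. The heat-shock list as a whole did not rise, with a median of −0.076 (SE over genes 0.18) over 21 tested heat-shock genes, of which 9 had a positive sign. The 2 of them past the threshold both fell, Hspb1 by 2.00 and Cryab by 3.13 on the log2 scale (limma adjusted p = 0.013 and 0.026). Both were named after their values were seen. Whether they fell in marrow cells or along with muscle, bone and stromal RNA was not tested, so their fall decides nothing about handling. Hspb1 lost its call without Onway 2 (0.068) or Onway 3 (0.054), and Cryab without Control 4 (0.099), Onway 1 (0.082), Onway 2 (0.11) or Onway 3 (0.10). Other differences in handling and a response of marrow cells to Onway were not tested and stay open, and the deposited Control mean leaves 257 TPM of Fos for a value labelled Control.

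The rise of Rpl17-ps5 was tested as reads shared with Rpl17. The summed TPM of both was 1067 ± 95.7 in Control and 1068 ± 62.6 in Onway (log2 ratio 0.00021, error 0.086, n = 3 per group), while Rpl17 differed by −269 TPM and Rpl17-ps5 by 269 TPM. This is consistent with reads assigned to another copy in the Onway libraries, without a change in their total. The deposited means leave 263 TPM of Rpl17-ps5 for the further value in Control and 13.6 TPM for that in Onway, with Rpl17 at 778 and 1020 TPM, so the switch did not follow the group labels. What it follows was not tested.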

How the results depend on the processing

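Of the called genes, 214 of the 424 lower and 8 of the 33 higher genes stayed past the threshold in all 6 such fits. Leaving out 1 library gave 16 to 87 higher genes, 246 to 456 lower genes and 22 to 28 lists past the threshold against 24. Higher genes numbered 61 with median-of-ratios scaling, 20 with the stricter filter, 21 with limma's treat and 56 with transcripts tested in place of genes, and lower genes 187 with the stricter filter, which tests fewer genes, and 280 with transcripts. Chosen after seeing the data, leaving out Control 4 and Onway 3 gave 97 higher and 207 lower genes, and the haemoglobin covariate gave 66 higher genes. Of the 24 lists, 0 passed with an estimated correlation and 8 with fry. Where a list was past the threshold before or after, its camera direction, set by the mean of its members, turned for mature neutrophil genes (median −0.10 without Control 4, range −0.10 to 0.75), erythroid genes (0.47 without Control 4 and 0.26 without Onway 2, range −0.40 to 0.47) and heme biosynthesis genes (0.39 without Control 4, range −0.31 to 0.39). The last 2 had means just below 0 and medians of 0.03 and 0.02, so their medians turned instead without Control 5 (−0.40 and −0.31) and without Onway 3 (−0.21 for erythroid genes). Other medians near 0 changed sign with scaling, with no list past the threshold. Except for the filter, the cause was not tested. Over all alternatives, named genes stayed on their side of the threshold in 2760 cases, passed it anew in 89 and lost it in 131. In 21 cases, over 13 genes, the sign changed, in 0 of them past the threshold. Count-based tests and voom-weighted camera were planned but not run, because TPM values are not counts, and scaling by library totals alone equals the values as used. Depth is unknown, so what it limits cannot be given.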

Other observations

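Single genes of the marrow niche, which holds and feeds stem cells, differed between the groups, while the list as a whole did not pass. Cxcl12, the chemokine that retains stem cells in marrow, fell from 195 ± 79.5 to 24.7 ± 7.73 TPM (limma with Benjamini-Hochberg adjusted p = 0.0059, n = 3 per group). Spp1 and Vcam1, described with bone and macrophage genes, and Kitl, the ligand of Kit (3.57 ± 0.965 against 0.513 ± 0.107 TPM, adjusted p = 0.012), also fell. Cxcr4, the receptor of Cxcl12, rose from 167 ± 21.2 to 302 ± 22.6 TPM (adjusted p = 0.047), and lost its call without any 1 of the 6 libraries (0.069 to 0.19). Kitl lost its call without Control 6 (0.056), Onway 2 (0.061) or Onway 3 (0.055). Kitl and Cxcr4 were named after their values were seen. Of the 18 tested growth factor and niche genes 5 fell and 1 rose, 5 and 2 adjusted over the list alone. Their median log2 fold change was 0.06 and their mean −0.48, with 9 members of each sign (camera adjusted p = 0.28).

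Single genes passed in other lists that did not. Cyp1b1, a cytochrome P450 of xenobiotic metabolism that stromal cells carry, fell from 6.98 ± 2.07 to 0.280 ± 0.0361 TPM (adjusted p = 0.0014, 1 of 10 xenobiotic response genes, also adjusted over the list alone, camera adjusted p = 0.95). Srxn1, an antioxidant enzyme and NRF2 target, fell from 8.74 ± 1.22 to 3.20 ± 0.317 TPM (adjusted p = 0.012, 1 of 27, camera adjusted p = 0.16 and 0.039 without Onway 1), and lost its call without Control 6 (0.070) or Onway 1 (0.052). Cd209a, a lectin of dendritic cells, rose from 1.35 ± 0.260 to 4.68 ± 1.34 TPM (adjusted p = 0.027, 1 of 14 dendritic cell genes). It lost its call without any 1 library but Control 4 (0.060 to 0.099). Adjusted over the list alone, 3 members rose and 2 fell, and 10 had a positive and 4 a negative sign. Of negative sign, Cox6a2 was at 44.7 TPM in Control (libraries 14.5 to 74.7 TPM) and 4.61 TPM in Onway. It passed without Control 5 (adjusted p = 0.00093). Whether it fell in dendritic cells or along with muscle RNA was not tested. The dendritic cell list had a camera adjusted p of 0.074, 0.039 without Onway 1 and 0.030 without Onway 2. Of the 13 mitochondrially encoded genes mt-Co3 fell (598 ± 151 against 286 ± 22.9 TPM, adjusted p = 0.047, camera adjusted p = 0.069, and 0.016, 0.040 and 0.029 without Control 5, Onway 1 and Onway 2), and it lost its call without any 1 of the 6 libraries (0.073 to 0.15). Of 20 eosinophil, basophil and mast cell genes none passed, 2 adjusted over the list alone, and Ear2 was at 1099 ± 301 and 2349 ± 859 TPM (adjusted p = 0.23, camera adjusted p = 0.27, and 0.016 without Control 5).

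Of 222 tested immunoglobulin variable segments 200 had a positive sign and 5 rose. With transcripts tested in place of genes, 1 transcript of Ighv13-2 fell by 3.06 on the log2 scale (adjusted p = 0.024), named after its value was seen, while the gene did not pass (adjusted p = 0.12). Among Gene Ontology terms, 155 held more lower genes and 28 held more higher genes than independent draws of genes would give. The test was a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. It takes genes as independent, while members of a list moved together (estimated correlations 0.94 for muscle and 0.69 for platelet genes). Its p-values describe the make-up of the called genes and do not measure the spread between libraries. Lower genes included 37 of 93 extracellular matrix genes (2.92 expected, adjusted p = 3.5e-28), 22 of 85 genes of the muscle Z disc (adjusted p = 3.7e-12), 16 of 58 ossification genes (adjusted p = 3.1e-09) and 13 of 52 blood coagulation genes (adjusted p = 5.8e-07). Higher genes included 4 of 34 genes of the response to cAMP (adjusted p = 0.00078) and 3 of 22 that bind AU-rich mRNA ends (adjusted p = 0.0034).

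Written before its result was seen, a test of other splits of the 6 libraries into 3 and 3 found 1 of 10 splits with as many genes past the threshold, the split by treatment itself, with 457 genes against at most 18. With 10 splits, a share under 0.05 cannot be reached.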
